A study of Homo sapiens with 18 samples.

How the data were processed

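The series measured RNA from MCF7 cells in 18 polyA-selected, stranded RNA-seq libraries, 3 for each of 6 groups. The authors deposited a table of gene counts and a table of FPKM values over the same 23393 gene symbols and the 18 libraries. The counts are whole numbers of reads per gene without normalization, as the values of the deposited table show. The tools named per the submitters' processing notes are bcl2fastq 1.8, TopHat2 2.0.14 and HTSeq 0.6.0, with the genome build hg19; the notes give these tools and the build no role, and the gene annotation is not given in the sources used here. The FPKM values deposited by the authors are normalized for gene length and library size, and their denominators are not given in the sources used here. All 38623 FPKM values above 20 have a log2(FPKM + 0.1) within 0.001 of a number with 2 decimals, so they appear to be rounded on that scale. Of the values listed at 0, 2444 have a count above 0. The FPKM table served only for alternative settings and for relative gene length, taken as the ratio of counts to FPKM. The reference annotation at hand is of another build, so no coordinates are given and genes are named by symbol.

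Library totals were 20413030 to 27176511 counts. A gene entered the tests if it passed edgeR's filterByExpr on the groups. 14287 genes did, and at most 0.0357% of a library's counts lay in the genes left out. Each comparison used edgeR 4.0.16 (R 4.3.3): TMM factors, quasi-likelihood fit and F test (two-sided) on all 18 libraries with a mean for each group and a term for the batch given in the labels. PBDE47 replicate 3 is the only library of batch2, so this term leaves the PBDE47 comparisons to its 2 batch1 libraries. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and genes with adjusted p under 0.05 were called. SE and 95% intervals come from the same fits, and a prior count of 2 was used for log2 CPM per library. Over genes with a mean above 10 CPM, the median SE of a log2 fold change was about 0.061 (0.0683 and 0.0678 for PBDE47 against Control and PPT). Levels in CPM are TMM-scaled. Intervals cover the spread between these libraries only.

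Gene lists were written before the data were examined. They cover estrogen-induced and estrogen-repressed genes, receptors and coregulators, DNA replication, mitosis, ribosome biogenesis, targets of AhR, PXR and CAR, NRF2, LXR, PPAR and p53, the integrated stress response, endoplasmic reticulum chaperones, cholesterol and fatty acid synthesis, the BCL2 family, thyroid hormone response, hypoxia, respiratory chain, heat shock proteins, metallothioneins, interferon response, NF-kB, steroid metabolism, markers of luminal, basal, fibroblast, immune and endothelial cells, histones and mitochondrially encoded genes. Lists with at least 4 tested members, 28 of 32, were tested with camera (limma 3.58.1, preset correlation 0.01), which compares a list with the other genes, and the adjusted p-values run over the lists of a comparison. The same test with a correlation estimated from the data, and fry, which asks whether the members move on balance 1 way, were alternatives. Beside the count of changed members over all genes tested stands the count adjusted over the list alone. The mean log2 CPM of the estrogen-induced list per library was compared by exact two-sided permutation. For comparisons that share libraries, shares of direction, correlations and covariances were set beside 20 simulations of unchanged groups against the shared libraries, and counts of shared calls beside the overlap of independent lists.

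Genes were named by a rule fixed before the data were examined. It takes the 10 risen and 10 fallen genes of largest fitted fold change (5 and 5 outside the comparisons of PPT and PBDE47 with Control and of the 3 combinations with PPT) among called genes with a mean of at least 1 CPM and no overlap between the libraries of the groups. Chance puts 10% of genes without overlap at 3 against 3 libraries. It adds TFF1, PGR, GREB1, PDZK1, CXCL12, MYC, CCND1, ESR1, CYP1A1 and CYP1B1 in every comparison, and from each list described up to 4 called members of smallest p and up to 2 uncalled members of highest level. Genes with near-identical copies are named with that limit.

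Alternatives written before the data were examined were DESeq2 size factors, upper-quartile factors or library size alone in edgeR, no filter or a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with and without a filter of at least 1 FPKM in at least 3 libraries, no batch term, the replicate number as a block, only the 2 groups compared, each library left out in turn, adjusted p under 0.01 and a test for changes over 1.5-fold. Setting PPT+PBDE100 replicate 2 aside and removing the trend with gene length were added after its deviation was seen.

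The edgeR and list tests were checked on simulated counts for 14136 genes with the means, library sizes and spread of the real libraries. In a simulated PPT+PBDE153 against PPT, 29, 40, 42 and 47 of 50 genes changed 1.25-, 1.5-, 2- and 3-fold were recovered, with 7 false calls. In a simulated PBDE47 against Control, 29, 39, 45 and 49 of 50 were recovered, with 15 false calls. An interferon list shifted in simulation was called (camera adjusted p = 8.0e-15), and no other of the 27 lists tested was. Counts were drawn gene by gene, without correlation between genes and without a length trend. The check thus does not show how the list test behaves when members move together.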

Results

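The data were gene-level RNA-seq measurements of MCF7 cells, a human breast cancer line that expresses estrogen receptor alpha and proliferates in response to estrogen. The cells were kept for 2 days in medium low in steroid hormones and then exposed for 24 h. The 18 polyA-selected, stranded libraries formed 6 groups of 3. Control cells received 0.2% DMSO. The reference agonist was PPT at 10 nM, a compound selective for estrogen receptor alpha, and the reference antagonist was MPP at 1 µM, given together with PPT. The treatment protocol writes MMP at this dose, which was taken as the same compound. Polybrominated diphenyl ethers (PBDEs), a class of brominated flame retardants, were given at 20 µM. PBDE47, a tetrabrominated congener, was given alone, whereas the pentabrominated PBDE100 and the hexabrominated PBDE153 were given together with PPT. Library totals ran from 20413030 to 27176511 counted reads over 23393 genes. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Unless stated otherwise, levels are CPM (counts scaled by effective library size, mean ± SD, n = 3), changes are fitted log2 fold changes ± SE, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For gene lists, the median log2 fold change of the tested members is given with camera's adjusted p-value. Called lists whose call was lost with an estimated correlation carry that p-value too, and the other called lists described held with it. Outside PPT against Control, not every called list is described. The preset correlation can understate how far members move together. Estimating it cut the called lists from 12 to 6 for PBDE47 against Control and from 15 to 6 for PPT+PBDE100 against PPT. Very small camera p-values should therefore not be read as the strength of evidence from these libraries. Genes are identified by their symbols in the deposited tables.

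No pair of replicates agreed within sampling noise: the chi-square per degree of freedom over genes ran from 1.32 to 34.6. One library stood apart. PPT+PBDE100 replicate 2 deviated from its group with an SD of 0.277 on the log2 scale across genes, against 0.150 and 0.152 for the other libraries of that group and 0.0666 to 0.111 for the libraries of the other groups. Its deviation followed gene length, with a median of 0.30 in the shortest of 5 equal length classes of the expressed genes and -0.30 in the longest. Because all groups share 1 estimate of the spread, counts of changed genes are given with and without this library. This was done for PPT and PBDE47 against Control and for the combinations against PPT. The labels assign PBDE47 replicate 3, and no other library, to a second batch, so comparisons of PBDE47 rest on its 2 libraries of the first batch and the pooled values are given beside them.

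**Figure D1:**
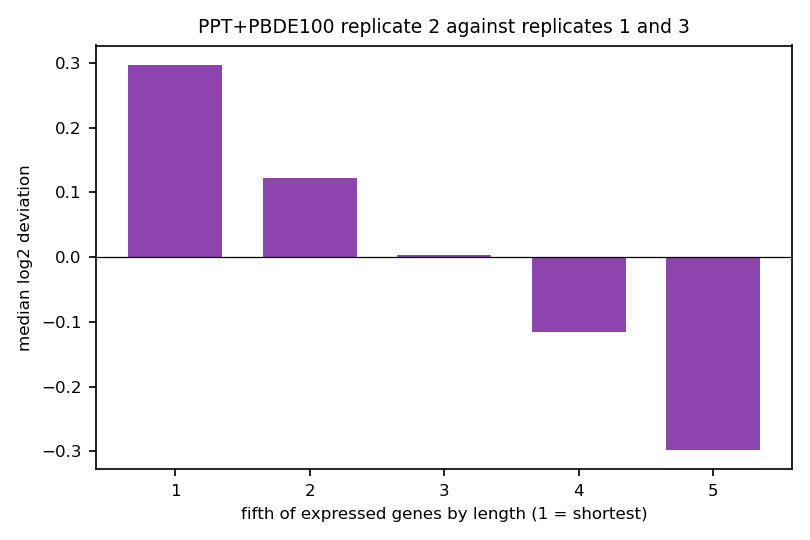
Median log2 deviation of PPT+PBDE100 replicate 2 from the mean of replicates 1 and 3 of its group (y axis) in 5 classes of 9523 expressed genes ordered by relative gene length (x axis, shortest first). The medians fall from 0.30 in the shortest class to -0.30 in the longest.

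The comparison of PPT with Control asked which genes the agonist moved. PPT raised the classical estrogen-regulated genes and the genes of the cell cycle, and lowered estrogen-repressed genes. PGR, the progesterone receptor gene, rose from 29.8 ± 5.13 to 490.0 ± 7.89 CPM (log2 fold change 4.04, SE 0.14, adjusted p = 1.1e-14). CXCL12, a chemokine gene, rose from 13.3 ± 0.144 to 118 ± 0.279 CPM (log2 fold change 3.15, SE 0.058, adjusted p = 2.7e-18). TFF1, which encodes a secreted trefoil peptide, rose from 128 ± 11.99 to 441 ± 19.2 CPM (log2 fold change 1.78). GREB1, an estrogen receptor cofactor gene, rose from 728 ± 26.2 to 2378 ± 2.13 CPM (1.71), and PDZK1, a scaffold protein gene, from 4.76 ± 0.274 to 31.3 ± 1.43 CPM (2.71). ESR1, which encodes estrogen receptor alpha itself, fell from 1146 ± 17.7 to 621 ± 6.45 CPM (-0.88). MYC and CCND1, drivers of entry into the cell cycle, rose with log2 fold changes of 0.84 ± 0.087 and 0.45 ± 0.032.

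All 36 tested members of the estrogen-induced list rose (median 1.53, camera adjusted p = 9.3e-33). MYBL1 (3.32 ± 0.073), RAPGEFL1 (2.51 ± 0.042) and the receptor tyrosine kinase gene RET (2.01 ± 0.043) were among them. All 17 tested members of the estrogen-repressed list fell (median -1.98, camera adjusted p = 7.1e-27). ERBB2, the HER2 receptor gene, fell from 248 ± 7.09 to 73.9 ± 0.4503 CPM, and the antiproliferative gene BTG2 by a log2 change of -2.06 ± 0.050. The counts adjusted over the list alone were the same. The mean level of the estrogen-induced list, as log2 CPM per library, was 5.20 ± 0.036 in Control and 6.88 ± 0.029 in PPT, a difference of 1.68 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give).

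Of 40 tested DNA replication (G1/S) genes, 39 rose and 1 fell (median 1.85, camera adjusted p = 5.5e-57). All 37 mitosis (G2/M) genes rose (median 2.67, camera adjusted p = 1.0e-101). Both counts were the same adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, rose from 60.01 ± 7.04 to 379 ± 10.7 CPM, and CCNA2, which encodes cyclin A2, from 24.9 ± 2.06 to 174 ± 4.003 CPM. The spindle genes DLGAP5 and NDC80 rose by 2.75 ± 0.046 and 2.84 ± 0.051 on the log2 scale. All 24 ribosome biogenesis genes rose (24 adjusted over the list alone) (median 0.73, camera adjusted p = 1.8e-08, adjusted p = 0.0529 with an estimated correlation). NOLC1 and NOP56 were at 0.86 ± 0.035 and 1.12 ± 0.049. Of 24 cholesterol synthesis genes, 20 rose and 0 fell (20 and 0 adjusted over the list alone) (median 0.69, camera adjusted p = 2.5e-06, adjusted p = 0.0529 with an estimated correlation). They included DHCR7 (0.96 ± 0.041) and FDFT1 (1.07 ± 0.048), while SREBF2, the regulator of the pathway, was at 0.024 ± 0.056 (adjusted p = 0.712). In the integrated stress response list 18 rose and 6 fell of 27 tested members (18 and 6 adjusted over the list alone) (median 0.63, camera adjusted p = 6.6e-04, adjusted p = 0.263 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, rose (2.20 ± 0.063) and DDIT4, an inhibitor of mTORC1 signalling, fell (-2.48 ± 0.050). Of the heat shock proteins, 10 rose and 1 fell of 15 tested members (10 and 1 adjusted over the list alone) (median 0.65, camera adjusted p = 6.2e-04, adjusted p = 0.237 with an estimated correlation). HSPH1 was at 1.08 ± 0.032 and BAG3 at -0.93 ± 0.041.

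Further lists moved downward. Among apoptosis regulators of the BCL2 family 4 rose and 9 fell of 15 tested members (4 and 9 adjusted over the list alone) (median -0.13, camera adjusted p = 0.005998). The fallen members included the pro-apoptotic genes BMF, from 180.2 ± 8.32 to 19.5 ± 1.102 CPM, and BIK (-2.82 ± 0.18). For PPAR targets, 2 rose and 12 fell of 17 tested members (2 and 12 adjusted over the list alone) (median -0.43, camera adjusted p = 0.00918). TXNIP was at -1.35 ± 0.041. For LXR targets, 0 rose and 6 fell of 7 tested members (0 and 6 adjusted over the list alone) (median -0.48, camera adjusted p = 0.00168). The cholesterol exporter gene ABCG1 fell (-2.43 ± 0.076). For replication-dependent histones, 3 rose and 10 fell of 13 tested members (3 and 10 adjusted over the list alone) (median -1.46, camera adjusted p = 5.8e-07). HIST2H2BE fell from 278 ± 12.7 to 50.7 ± 0.834 CPM, but histone copies share near-identical sequence and most of their transcripts lack polyA tails, so these counts are uncertain. In the interferon response list 1 rose and 15 fell of 19 tested members (1 and 15 adjusted over the list alone), but the list as a whole was not called (median -0.78, camera adjusted p = 0.113). IFI44L (-1.87 ± 0.17) and IFITM1 (-0.97 ± 0.17) fell, and IRF7 was at 0.067 ± 0.10 (adjusted p = 0.569). AhR targets went both ways: 4 rose and 3 fell of 7 tested members (4 and 3 adjusted over the list alone) (median 0.94, camera adjusted p = 0.6997). CYP1A1, which encodes the xenobiotic-metabolising P450 enzyme most responsive to the aryl hydrocarbon receptor (AhR), fell from 5.29 ± 0.262 to 1.24 ± 0.428 CPM, whereas CYP1B1, whose product hydroxylates estradiol, rose from 16.3 ± 1.38 to 34.6 ± 6.900 CPM.

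The remaining lists were not called for PPT, or only narrowly. For NRF2 targets 13 rose and 4 fell of 22 tested members (13 and 4 adjusted over the list alone) (median 0.24, camera adjusted p = 0.0488, adjusted p = 0.381 with an estimated correlation). The call was lost without Control replicate 1 (adjusted p = 0.0576) or 3 (0.0504), without PPT replicate 2 (0.0578) and with library-size scaling (0.0627). Risen and fallen members numbered 4 and 7 of 16 tested receptor and coregulator genes, with NRIP1 rising (1.70 ± 0.10) and GPER1, the membrane estrogen receptor gene, falling (-1.30 ± 0.044). They numbered 8 and 11 of 22 p53 targets, 8 and 3 of 13 steroid metabolism genes, 2 and 6 of 11 luminal markers, 18 and 1 of 24 nuclear respiratory chain genes, 7 and 5 of 19 hypoxia genes, 0 and 4 of 5 NF-kB genes, 4 and 5 of 11 thyroid hormone response genes, 11 and 6 of 21 endoplasmic reticulum chaperones, 8 and 1 of 14 fatty acid synthesis genes, 0 and 1 of 4 metallothioneins, 2 and 4 of 10 basal markers and 1 and 0 of 4 immune markers. Adjusted over the list alone, the counts were 9 and 11 for p53 targets, 8 and 4 for steroid metabolism, 2 and 3 for basal markers and 0 and 0 for immune markers, and the same for the others. The camera adjusted p-values of these 13 lists ran from 0.0813 for the respiratory chain to 0.978 for immune markers. Too few members were tested for a list test of PXR and CAR targets (0 and 0 of 3 changed), fibroblast markers (2 and 1 of 3) and endothelial markers (0 and 2 of 3), and the tables held none of the 11 mitochondrially encoded genes.

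By size of change, the risen genes were led by the imprinted RNA H19 (6.67 ± 0.2097 CPM in PPT and 0.0899 ± 0.00185 in Control), FGFBP2, CALB2 (from 2.103 ± 0.482 to 71.1 ± 1.45 CPM), the transcription factor gene EGR3 (4.87 ± 0.16), PCP4, KIAA0125, GATA4, the matrix protein gene MGP (4.12 ± 0.13), PGR and BMPER. The fallen genes were led by EPHB1 (0.111 ± 0.0185 CPM in PPT and 3.59 ± 0.166 in Control), MME, which encodes the peptidase neprilysin (from 85.1 ± 0.5103 to 4.41 ± 0.461 CPM), DLGAP1, the interleukin 1 receptor gene IL1R1 (-4.16 ± 0.13), NAV3, ITGB6, KIF26B, CLIC5, CHGA and CHRD. Fitted folds of genes under 1 CPM in 1 group depend on the prior count. In total, 9995 of 14287 tested genes changed, 4976 upward and 5019 downward, and 1035 and 1299 of them by at least 2-fold. With upper-quartile and library-size scaling 41.5% and 41.2% of calls were upward, against 49.8%. Setting PPT+PBDE100 replicate 2 aside gave 11067 changed genes. Markers of other cell types stayed low: the summed level of 10 fibroblast markers was 12.4 ± 1.68 CPM in Control and 18.4 ± 1.41 in PPT, and that of 11 luminal epithelial markers 11600.5 ± 212 and 9747 ± 119 CPM.

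**Figure D2:**
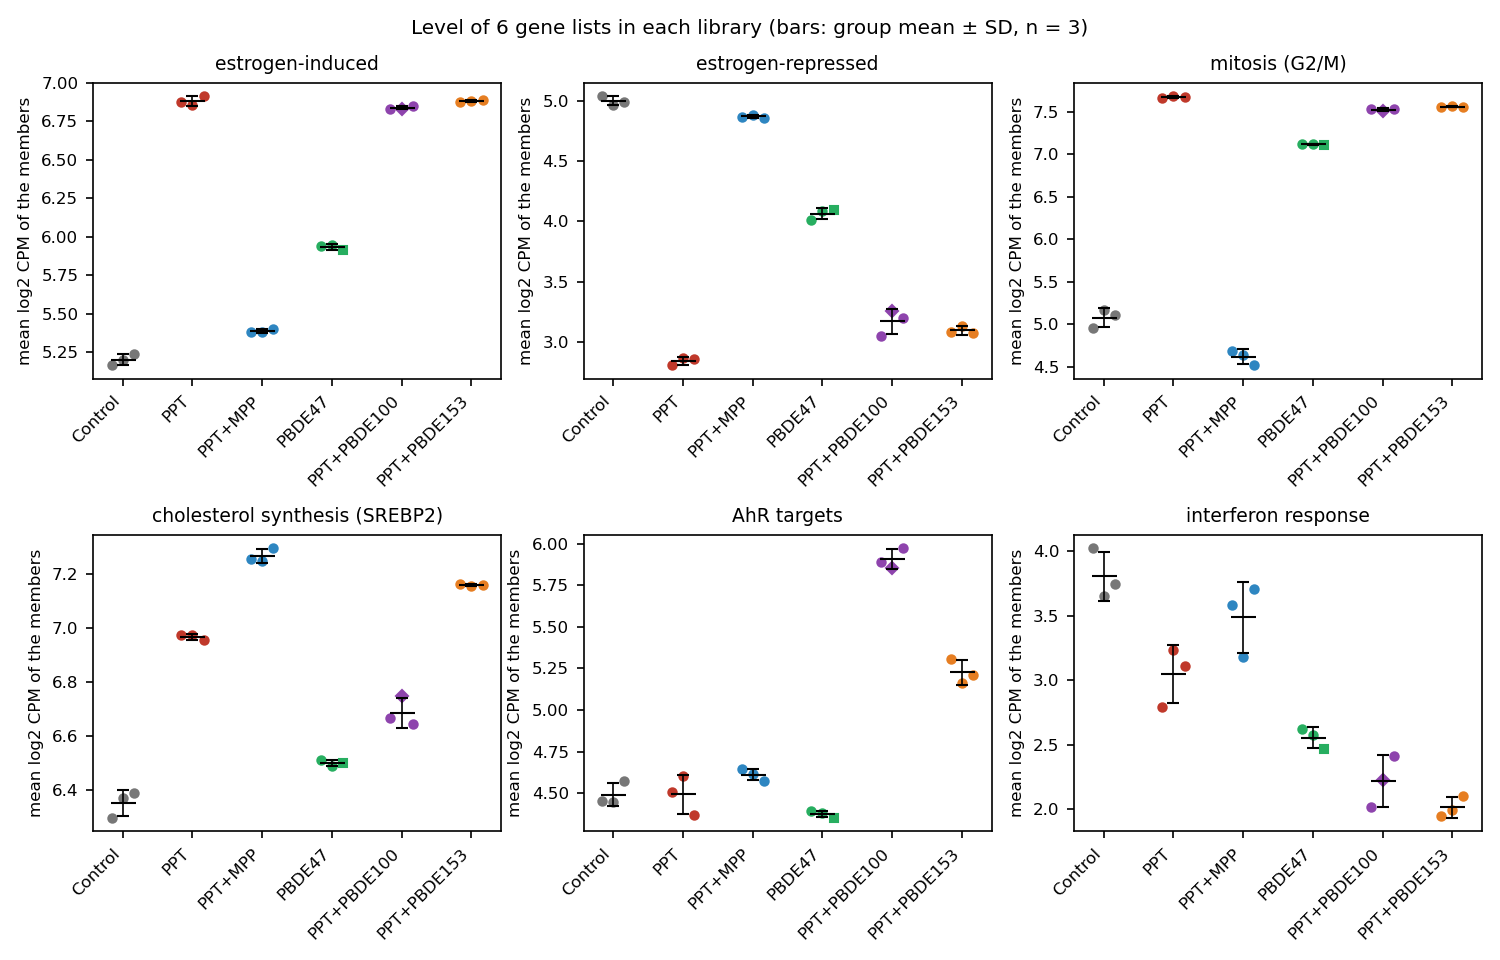
Mean log2 CPM of the tested members of 6 gene lists in each library (points) by group, with bars for the group mean ± SD (n = 3); squares mark PBDE47 replicate 3 of the second batch and diamonds PPT+PBDE100 replicate 2. The estrogen-induced list stands at 5.20 in Control, 6.88 in PPT, 5.39 in PPT+MPP and 5.93 in PBDE47.

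PBDE47 was tested alone because an estrogen-like action was anticipated for it. At 20 µM it raised estrogen-induced and cell cycle genes and lowered estrogen-repressed genes, the same directions as PPT, with interferon response genes also falling (a list call lost with an estimated correlation, adjusted p = 0.332). PGR rose from 29.8 ± 5.13 to 104 ± 3.23 CPM (log2 fold change 1.803, SE 0.15, adjusted p = 1.1e-08). TFF1 rose from 128 ± 11.99 to 229 ± 4.48 CPM (log2 fold change 0.83, SE 0.093, adjusted p = 6.7e-07) and CXCL12 from 13.3 ± 0.144 to 52.2 ± 1.06 CPM (1.98). Levels in the first batch alone (n = 2) were 104 ± 4.37 CPM for PGR and 228 ± 5.65 CPM for TFF1, against 106 and 231 CPM in the single library of the second batch. MYC rose from 120.5 ± 1.35 to 265 ± 10.8 CPM (1.16 ± 0.095), PDZK1 rose by 1.251 ± 0.094 and CCND1 by 0.13 ± 0.035 on the log2 scale, and ESR1 fell (-0.50 ± 0.068). GREB1 was at 0.26 ± 0.10 with adjusted p = 0.0383, a call lost when any 1 Control library or either first-batch PBDE47 library was left out (adjusted p from 0.0562 to 0.168) and with upper-quartile (0.105) or library-size scaling (0.0571). Upper-quartile scaling also ended the call of CCND1 (adjusted p = 0.111).

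Of 36 estrogen-induced genes, 31 rose and 0 fell (31 and 0 adjusted over the list alone) (median 0.69, camera adjusted p = 1.8e-13). MYBL1 (1.797 ± 0.082), RAPGEFL1 (1.17 ± 0.048) and RET (1.07 ± 0.048) were among them. Of 17 estrogen-repressed genes, 0 rose and 16 fell (0 and 16 adjusted over the list alone) (median -0.97, camera adjusted p = 4.9e-16). ERBB2 fell from 248 ± 7.09 to 143 ± 2.02 CPM. The list level was 5.93 ± 0.018 with all 3 PBDE47 libraries and 5.94 in the first batch, differences from Control of 0.73 and 0.74 (exact two-sided permutation p = 0.1 for the 3 libraries, the smallest possible). For G1/S genes, 39 rose and 0 fell of 40 tested members (39 and 0 adjusted over the list alone) (median 1.54, camera adjusted p = 3.4e-102). For mitosis genes, 37 rose and 0 fell of 37 tested members (37 and 0 adjusted over the list alone) (median 2.11, camera adjusted p = 1.7e-162). RRM2 rose from 60.01 ± 7.04 to 258 ± 1.11 CPM, DLGAP5 from 34.3 ± 0.476 to 154 ± 7.95 CPM, and the mitotic kinase gene AURKB from 15.5 ± 2.39 to 88.6 ± 1.94 CPM.

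In the interferon response list 0 rose and 17 fell of 19 tested members (0 and 17 adjusted over the list alone) (median -1.15, camera adjusted p = 3.9e-05, adjusted p = 0.332 with an estimated correlation). IFI44L fell from 17.6 ± 4.36 to 2.75 ± 0.168 CPM, and IFIT1, which encodes a sensor of viral RNA, from 25.1 ± 4.96 to 4.701 ± 1.097 CPM. OAS1, whose product starts RNase L activation, fell by a log2 change of -2.17 ± 0.28, while USP18 was at 0.11 ± 0.10 (adjusted p = 0.387). Of the ribosome biogenesis genes, 22 rose and 0 fell of 24 tested members (22 and 0 adjusted over the list alone) (median 0.35, camera adjusted p = 8.5e-05, adjusted p = 0.229 with an estimated correlation). In the integrated stress response list 17 rose and 3 fell of 27 tested members (18 and 3 adjusted over the list alone) (median 0.38, camera adjusted p = 2.2e-04, adjusted p = 0.302 with an estimated correlation). PHGDH was at 1.68 ± 0.068 and DDIT4 at -1.12 ± 0.052. For histones, 1 rose and 10 fell of 13 tested members (3 and 10 adjusted over the list alone) (median -0.90, camera adjusted p = 1.0e-06), with the same limit on their counts. LXR targets fell in part: 0 rose and 4 fell of 7 tested members (0 and 4 adjusted over the list alone) (median -0.29, camera adjusted p = 5.3e-04). AhR targets were not called as a list: 3 rose and 3 fell of 7 tested members (3 and 3 adjusted over the list alone) (median -0.30, camera adjusted p = 0.767). CYP1A1 fell (-1.21 ± 0.20) and CYP1B1 was at -0.30 ± 0.15 (adjusted p = 0.125; 0.0472 with replicate 3 pooled, 0.00367 with only these 2 groups fitted and 0.0376 with PPT+PBDE100 replicate 2 set aside). CYP19A1, which encodes aromatase, stood at 643 ± 23.2 CPM in Control and 783 ± 19.6 in PBDE47 (0.30 ± 0.063).

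The genes that rose most were H19, FGFBP2, CALB2 (from 2.103 ± 0.482 to 20.3 ± 1.76 CPM), the DNA repair gene RAD54L (2.55 ± 0.065), AURKB, MNS1, PIF1, KIF18B, KIF15 and CDCA3, and those that fell most were EPHB1, IFI44L, CHGA, RCAN2, IFIT1, OAS1, BST2, OAS2, IFI44 and LRRC15. In total 6762 genes changed, 3441 upward and 3321 downward, 588 and 316 of them by at least 2-fold. With replicate 3 pooled and no batch term the count was 7255 (3673 upward, 3582 downward), 6495 of them shared. In replicate 3 itself 6656 of the 6762 genes, 98.4%, lay on the same side of Control. The calls were made against the same Control libraries, which raises this share, and no share for unchanged groups was simulated for it. The second batch has 1 library and no Control, so it gives no test of its own. With upper-quartile scaling 39.8% of calls were upward, against 50.9%. Setting PPT+PBDE100 replicate 2 aside gave 8491 changed genes.

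Of the 9995 genes changed by PPT, 6198 changed in the same direction with PBDE47 and 66 in the opposite direction. Independent lists of these sizes would share 2365.1. With PPT+PBDE100 replicate 2 set aside, the same and opposite counts were 7674 and 174, where independent lists would give 3257.9 and 3258.3. Counting direction alone, 94.25% of the 9995 PPT-changed genes went the same way, against a mean of 53.03% for simulated unchanged groups that share simulated Control libraries. Across genes, which are not independent replicates, the fold changes correlated at 0.877 (0.0781 simulated), with a covariance of 0.396 against a simulated 0.0123. Part of the excess may come from the shared Control libraries, which are too few to split.

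**Figure D3:**
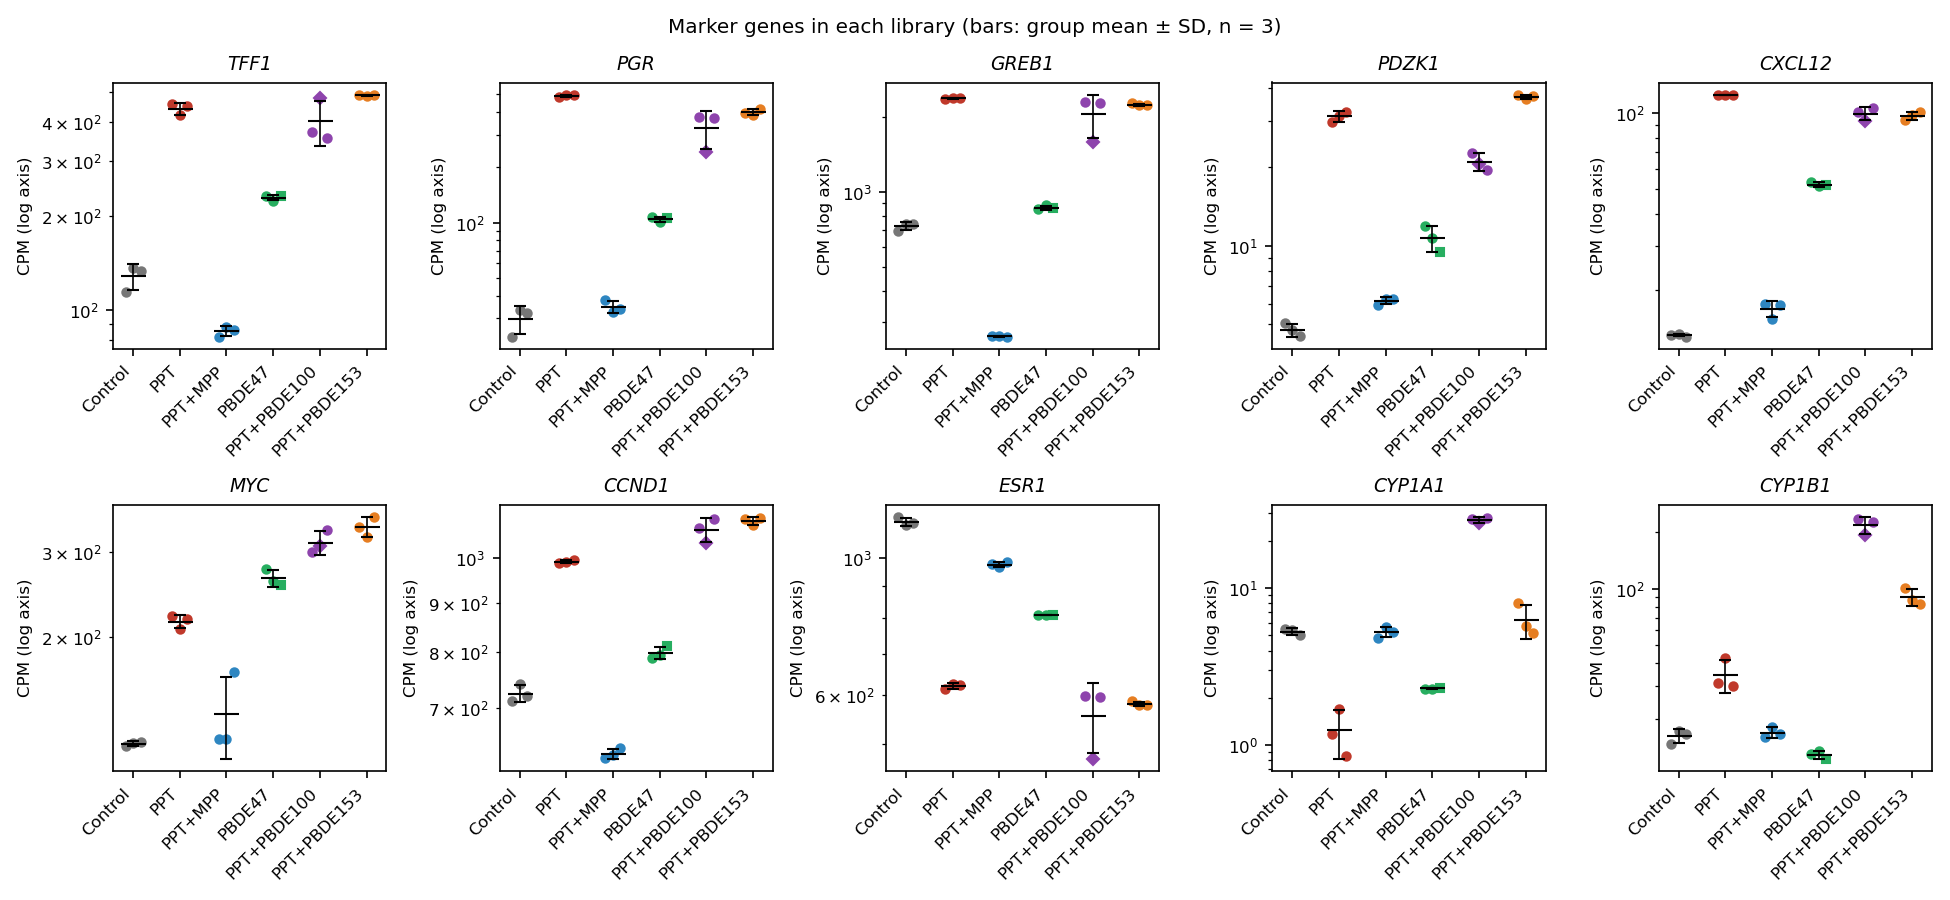
CPM (log axis) of the 10 genes named in every comparison, in each library by group, with bars for the group mean ± SD (n = 3); squares mark PBDE47 replicate 3 and diamonds PPT+PBDE100 replicate 2. PGR stands at 29.8 CPM in Control, 490.0 in PPT, 34.7 in PPT+MPP and 104 in PBDE47, and CYP1A1 at 27.1 CPM in PPT+PBDE100.

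The comparison of PPT+MPP with PPT asked how the reference antagonist changed expression in the presence of PPT. No group received MPP without PPT, so effects of MPP itself cannot be told apart from a reversal of the PPT response. With MPP, estrogen-induced and cell cycle genes were far below their level with PPT alone and estrogen-repressed genes far above it. PGR fell from 490.0 ± 7.89 to 34.7 ± 2.64 CPM (log2 fold change -3.82, SE 0.14, adjusted p = 1.5e-14) and GREB1 from 2378 ± 2.13 to 263 ± 0.825 CPM (log2 fold change -3.18, SE 0.10, adjusted p = 7.9e-16). TFF1 fell from 441 ± 19.2 to 85.7 ± 3.16 CPM (-2.36) and CXCL12 from 118 ± 0.279 to 16.9 ± 1.27 CPM (-2.80). PDZK1 (-2.34 ± 0.072), CCND1 (-0.66 ± 0.032) and MYC (-0.63 ± 0.086) also fell, ESR1 rose (0.65 ± 0.060), CYP1A1 rose (2.09 ± 0.20) and CYP1B1 fell (-1.03 ± 0.12).

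Of 36 estrogen-induced genes, 2 rose and 33 fell (2 and 33 adjusted over the list alone) (median -1.11, camera adjusted p = 8.6e-19). SIAH2, a ubiquitin ligase gene, fell from 308 ± 5.53 to 62.1 ± 0.637 CPM (-2.31 ± 0.048). All 17 estrogen-repressed genes rose (17 adjusted over the list alone) (median 2.01, camera adjusted p = 1.2e-19), ERBB2 from 73.9 ± 0.4503 to 248 ± 4.36 CPM. For G1/S genes, 1 rose and 39 fell of 40 tested members (1 and 39 adjusted over the list alone) (median -2.53, camera adjusted p = 1.0e-79). RRM2 fell to 29.5 ± 1.54 CPM. All 37 mitosis genes fell (37 adjusted over the list alone) (median -3.12, camera adjusted p = 3.3e-108). CCNA2 was at 17.2 ± 0.845 CPM. All 24 ribosome biogenesis genes fell (24 adjusted over the list alone) (median -0.91, camera adjusted p = 1.9e-10). For apoptosis regulators 10 rose and 4 fell of 15 tested members (10 and 4 adjusted over the list alone) (median 0.18, camera adjusted p = 0.0299, adjusted p = 0.0733 with an estimated correlation), a call lost with PPT+PBDE100 replicate 2 set aside (adjusted p = 0.0653). BMF rose from 19.5 ± 1.102 to 227 ± 4.05 CPM. For PPAR targets 11 rose and 3 fell of 17 tested members (11 and 3 adjusted over the list alone) (median 0.66, camera adjusted p = 0.00346). TXNIP rose (1.93 ± 0.041). For LXR targets 6 rose and 0 fell of 7 tested members (6 and 0 adjusted over the list alone) (median 0.71, camera adjusted p = 0.00745, adjusted p = 0.0733 with an estimated correlation). For histones 9 rose and 3 fell of 13 tested members (10 and 3 adjusted over the list alone) (median 1.46, camera adjusted p = 1.4e-06).

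The lipid synthesis lists were called higher with MPP than with PPT alone, but neither call held with an estimated correlation. The cholesterol list, which PPT had raised in a call also lost with an estimated correlation, was higher still with MPP. Of 24 tested members, 17 rose and 2 fell (17 and 2 adjusted over the list alone) (median 0.27, camera adjusted p = 0.0134, adjusted p = 0.339 with an estimated correlation). LSS, which forms lanosterol, rose from 255 ± 5.44 to 539 ± 25.7 CPM (1.08 ± 0.039) and HMGCS1, which acts early in the pathway, by a log2 change of 0.63 ± 0.037. In the fatty acid synthesis list 7 rose and 6 fell of 14 tested members (7 and 6 adjusted over the list alone) (median 0.19, camera adjusted p = 0.0189, adjusted p = 0.339 with an estimated correlation). The desaturase gene SCD rose from 3332 ± 10.3 to 7273 ± 133 CPM and the phosphatidate phosphatase gene LPIN1 from 89.7 ± 1.79 to 226 ± 3.08 CPM. Stress lists moved oppositely to PPT. In the integrated stress response list 6 rose and 18 fell of 27 tested members (6 and 18 adjusted over the list alone) (median -0.50, camera adjusted p = 0.0219, adjusted p = 0.486 with an estimated correlation). Among heat shock proteins 2 rose and 10 fell of 15 tested members (2 and 10 adjusted over the list alone) (median -0.63, camera adjusted p = 0.00222, adjusted p = 0.339 with an estimated correlation).

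The risen genes of largest change were SERPINA11, IL1R1 (from 0.764 ± 0.221 to 11.9 ± 0.912 CPM), NAV3, MME (3.70 ± 0.061), P2RX2, BMF, MYO15B, COL28A1, RIN2 and ABCC3, and the fallen ones BMPER (from 35.1 ± 0.614 to 0.505 ± 0.0894 CPM), KLK11, EGR3 (-4.79 ± 0.15), HAS2, ADORA1, PDLIM3, MYBL1, IL24, IL20 and IGSF1. In total 10383 genes changed, 5439 upward and 4944 downward, 1396 and 1172 by at least 2-fold. Setting PPT+PBDE100 replicate 2 aside gave 11384. Of the 9995 genes changed by PPT, 8908 moved in the opposite direction with MPP and 139 further in the same direction. Independent lists would give 3632.7 opposite genes. Both comparisons use the PPT libraries. Counting direction alone, 97.0% of the PPT-changed genes were opposite, against 53.6% for simulated unchanged groups. The correlation across genes was -0.91 (-0.0955 simulated) and the covariance -0.705 (-0.0143 simulated), of which the shared PPT libraries may supply a part.

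PBDE100 was given with PPT because an anti-estrogenic action was anticipated for it. AhR target genes rose in this combination and lipid synthesis genes fell. Interferon response genes also fell (a list call lost with an estimated correlation, adjusted p = 0.0619), while the mean level of the estrogen-induced list differed from PPT by -0.04 on the log2 scale. CYP1A1 rose from 1.24 ± 0.428 to 27.1 ± 1.18 CPM (log2 fold change 4.46, SE 0.16, adjusted p = 3.2e-12). CYP1B1 rose from 34.6 ± 6.900 to 219 ± 22.3 CPM (log2 fold change 2.67, SE 0.11, adjusted p = 1.7e-11). PGR fell from 490.0 ± 7.89 to 329 ± 76.3 CPM (-0.57 ± 0.12, adjusted p = 0.00419) and PDZK1 from 31.3 ± 1.43 to 20.9 ± 1.63 CPM (-0.58 ± 0.060, adjusted p = 5.0e-06). CXCL12 fell from 118 ± 0.279 to 99.4 ± 5.72 CPM (-0.24 ± 0.047, adjusted p = 0.00230) and MYC rose from 215 ± 6.86 to 314 ± 17.9 CPM (0.54 ± 0.085, adjusted p = 3.8e-04). TFF1 was at -0.14 (95% interval -0.31 to 0.035, adjusted p = 0.298), GREB1 at -0.21 (-0.39 to -0.024, adjusted p = 0.131) and ESR1 at -0.16 (-0.29 to -0.034, adjusted p = 0.0895).

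Some of these calls rested on single libraries. Without PPT+PBDE100 replicate 2, TFF1 fell (-0.28, adjusted p = 5.2e-08), ESR1 fell (-0.06, adjusted p = 0.0352), PGR was at -0.39 and GREB1 at -0.05 (adjusted p = 0.0628). GREB1 was called without PPT+PBDE100 replicate 1 (-0.30, adjusted p = 0.0321) or replicate 3 (-0.29, adjusted p = 0.0398). ESR1 was called in both fits too (adjusted p = 0.0266 and 0.0281). Both fits kept replicate 2, the library that stood apart. In replicates 1, 2 and 3 GREB1 stood at 2305, 1592 and 2281 CPM and ESR1 at 597, 472 and 596 CPM. The GREB1 calls thus rest on replicate 2. CCND1 was at 0.11 ± 0.032 (adjusted p = 0.0312), and its call was lost without PPT+PBDE100 replicate 1 (adjusted p = 0.0528) or replicate 3 (0.0834) and without PPT replicate 1, 2 or 3 (0.0919, 0.103 and 0.0886). Fitting only these 2 groups ended the calls of PGR (adjusted p = 0.114), CXCL12 (0.0836) and CCND1 (0.361).

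In the AhR list 5 rose and 0 fell of 7 tested members (5 and 0 adjusted over the list alone) (median 0.45, camera adjusted p = 1.6e-45). AHRR, the AhR repressor gene, rose from 5.702 ± 0.863 to 17.2 ± 1.92 CPM and the amino acid transporter gene SLC7A5 from 703 ± 13.5 to 963 ± 70.3 CPM. LRAT was at 0.33 ± 0.26 (adjusted p = 0.438). The steroid metabolism list, which shares CYP1A1 and CYP1B1 with it, was also called: 3 rose and 1 fell of 13 tested members (3 and 1 adjusted over the list alone) (mean log2 fold change 0.67) (median 0.075, camera adjusted p = 3.9e-11). In the cholesterol list 0 rose and 16 fell of 24 tested members (0 and 19 adjusted over the list alone) (median -0.28, camera adjusted p = 2.5e-28). INSIG1, a sterol-responsive gene, fell from 452 ± 6.99 to 330.4 ± 9.44 CPM. HMGCR, the rate-limiting enzyme gene, fell from 198 ± 3.36 to 138 ± 10.6 CPM and DHCR24 from 483 ± 5.29 to 357 ± 6.95 CPM. In the fatty acid synthesis list 1 rose and 9 fell of 14 tested members (1 and 11 adjusted over the list alone) (median -0.32, camera adjusted p = 1.6e-18). SCD fell from 3332 ± 10.3 to 2135 ± 224 CPM, FASN, the fatty acid synthase gene, from 2073 ± 47.5 to 1269 ± 169.5 CPM, and LPIN1 from 89.7 ± 1.79 to 61.7 ± 0.164 CPM.

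In the interferon response list 0 rose and 13 fell of 19 tested members (0 and 17 adjusted over the list alone) (median -0.76, camera adjusted p = 4.7e-14, adjusted p = 0.0619 with an estimated correlation). IFIT1 fell from 11.7 ± 3.34 to 2.704 ± 0.507 CPM and OAS3 from 93.7 ± 19.1 to 45.9 ± 7.67 CPM. Estrogen-repressed genes rose in part: 8 rose and 0 fell of 17 tested members (10 and 0 adjusted over the list alone) (median 0.27, camera adjusted p = 8.6e-08). MXD4, an antagonist of MYC, rose from 39.4 ± 2.07 to 51.99 ± 2.45 CPM. In the estrogen-induced list 6 rose and 10 fell of 36 tested members (8 and 14 adjusted over the list alone) (median -0.059, camera adjusted p = 0.01595, adjusted p = 0.147 with an estimated correlation). RET fell (-0.57 ± 0.039) and STC2 rose (0.33 ± 0.041). The level of the list per library was 6.84 ± 0.011, a difference from PPT of -0.04 (exact two-sided permutation p = 0.1, the smallest possible). In the mitosis list 0 rose and 16 fell of 37 tested members (0 and 21 adjusted over the list alone) (median -0.14, camera adjusted p = 3.4e-09, adjusted p = 0.211 with an estimated correlation), for example TPX2 (-0.22 ± 0.041) and AURKA (-0.20 ± 0.043), calls lost with only these 2 groups fitted (adjusted p = 0.0654 and 0.111). Apoptosis regulators were called: 1 rose and 1 fell of 15 tested members (1 and 1 adjusted over the list alone) (median 0.075, camera adjusted p = 0.009003). The risen member was BMF, from 19.5 ± 1.102 to 50.5 ± 2.86 CPM. Without PPT+PBDE100 replicate 2, risen and fallen members numbered 6 and 0 in the AhR list, 3 and 2 in steroid metabolism, 0 and 21 in cholesterol and 2 and 10 in fatty acid synthesis. They numbered 0 and 15 in the interferon response, 9 and 0 in the estrogen-repressed, 7 and 16 (of 37 tested) in the estrogen-induced, 0 and 27 in the mitosis and 2 and 2 in the apoptosis list.

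The risen genes of largest change were CYP1A1, CYP1B1, BFSP2, the immediate early gene EGR1 (1.78 ± 0.16), UGT2B15 (1.65 ± 0.16), AHRR, TNFRSF11B, PGM5, CD22 and BMF, and the fallen ones IFIT1, SAMD9, OAS2, DDX60, OAS1, PEG10 (from 1418 ± 10.3 to 641 ± 113 CPM), PARP9, IFIT3, OAS3 and FSTL5. UGT2B15 has near-identical copies that may share its reads, and the call of OAS2 was lost without PPT replicate 2 (adjusted p = 0.0659). That of IFIT3 was lost without PPT replicate 2 (adjusted p = 0.0615) or 3 (0.0955) and without PPT+PBDE100 replicate 1 (0.0612). With only these 2 groups fitted, SAMD9, DDX60, OAS1, IFIT3 and FSTL5 were not called (adjusted p from 0.0589 to 0.102). In total 1770 genes changed, 966 upward and 804 downward, 48 and 21 by at least 2-fold. The count was 3468 without PPT+PBDE100 replicate 2, 1065, 977 and 973 without PPT replicate 1, 2 and 3, and 203 when only these 2 groups were fitted. With library-size scaling 65.9% of calls were upward, against 54.6%.

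PBDE153 was given with PPT for the same reason, at the same 20 µM. Genes of the integrated stress response, cholesterol and fatty acid synthesis and metallothioneins rose, AhR targets rose less than with PBDE100, and interferon response genes fell. The interferon-induced gene IFIT1 fell from 11.7 ± 3.34 to 2.25 ± 0.468 CPM (log2 fold change -2.36, SE 0.31, adjusted p = 7.4e-05). OAS3 fell from 93.7 ± 19.1 to 37.6 ± 2.298 CPM (log2 fold change -1.32, SE 0.17, adjusted p = 6.2e-05). CYP1A1 rose from 1.24 ± 0.428 to 6.300 ± 1.54 CPM (2.35 ± 0.20, adjusted p = 4.7e-07) and CYP1B1 from 34.6 ± 6.900 to 90.2 ± 9.43 CPM (1.39 ± 0.11, adjusted p = 2.0e-07). Among estrogen-regulated genes, PDZK1 rose (0.25 ± 0.057, adjusted p = 0.00870) and CXCL12 fell (-0.27 ± 0.047, adjusted p = 0.00108). MYC rose from 215 ± 6.86 to 338 ± 15.7 CPM (0.65 ± 0.085, adjusted p = 7.1e-05) and CCND1 rose (0.14 ± 0.032, adjusted p = 0.00811). TFF1 was at 0.14 (95% interval -0.032 to 0.31, adjusted p = 0.316), PGR at -0.29 (-0.54 to -0.044, adjusted p = 0.131), GREB1 at -0.081 (-0.26 to 0.10, adjusted p = 0.622) and ESR1 at -0.10 (-0.22 to 0.029, adjusted p = 0.345). With PPT+PBDE100 replicate 2 set aside, which lowers the shared estimate of the spread, these 4 changes were called at nearly the same size (adjusted p = 4.9e-04 for TFF1, 3.2e-09 for PGR, 7.5e-04 for GREB1 and 5.3e-05 for ESR1).

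In the integrated stress response list 20 rose and 0 fell of 27 tested members (22 and 1 adjusted over the list alone) (median 0.33, camera adjusted p = 7.1e-37). ASNS, the asparagine synthetase gene, rose from 63.6 ± 2.68 to 101 ± 2.42 CPM and the cystine transporter gene SLC7A11 from 31.7 ± 1.01 to 62.1 ± 3.25 CPM. DDIT4 rose from 19.5 ± 0.779 to 35.6 ± 1.52 CPM and NUPR1 from 5.65 ± 0.582 to 14.03 ± 0.598 CPM. AARS was at 0.074 ± 0.032 (adjusted p = 0.159). In the cholesterol list 13 rose and 0 fell of 24 tested members (19 and 0 adjusted over the list alone) (median 0.19, camera adjusted p = 1.5e-15). INSIG1 rose from 452 ± 6.99 to 586 ± 4.91 CPM and LDLR, the LDL receptor gene, was at 0.092 ± 0.048 (adjusted p = 0.254). In the fatty acid synthesis list 7 rose and 0 fell of 14 tested members (8 and 0 adjusted over the list alone) (median 0.20, camera adjusted p = 5.3e-13). LPIN1 rose from 89.7 ± 1.79 to 125 ± 3.19 CPM, SCD from 3332 ± 10.3 to 4316 ± 26.4 CPM, and FASN was at 0.13 ± 0.066 (adjusted p = 0.226). AARS, LDLR and FASN were called with PPT+PBDE100 replicate 2 set aside (adjusted p = 0.00254, 0.00449 and 2.1e-05). Among metallothioneins 4 rose and 0 fell of 4 tested members (4 and 0 adjusted over the list alone) (median 0.58, camera adjusted p = 2.0e-05). MT2A was at 0.57 ± 0.093; these copies are similar in sequence and may share reads.

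In the interferon response list 0 rose and 14 fell of 19 tested members (0 and 18 adjusted over the list alone) (median -0.94, camera adjusted p = 5.6e-23). IFI6 fell from 130.5 ± 18.03 to 55.1 ± 2.36 CPM and USP18 was at -0.21 ± 0.087 (adjusted p = 0.136). Without any 1 PPT library in turn the median was -1.06, -0.89 and -0.89. In the AhR list 6 rose and 0 fell of 7 tested members (6 and 0 adjusted over the list alone) (median 0.33, camera adjusted p = 1.1e-16). AHRR rose from 5.702 ± 0.863 to 10.4 ± 0.763 CPM, below its 25.6 ± 1.67 CPM in Control. CYP1A1, raised by the combination against PPT, was near its Control level of 5.29 ± 0.262 CPM. For these genes a rise cannot be told apart from a loss of their fall with PPT. CYP1B1 lay above its Control level of 16.3 ± 1.38 CPM. Of the estrogen-repressed genes 6 rose and 0 fell of 17 tested members (7 and 0 adjusted over the list alone) (median 0.19, camera adjusted p = 9.8e-07). Of the estrogen-induced genes 5 rose and 7 fell of 36 tested members (5 and 9 adjusted over the list alone) (median 0.0044, camera adjusted p = 0.659). Their mean was -0.00099, of opposite sign to the median. The level of the latter list per library was 6.88 ± 0.0063, against 6.88 ± 0.029 in PPT (difference -0.0004, exact two-sided permutation p = 1). Within it STC2 rose (0.51 ± 0.041) and SLC9A3R1 fell (-0.37 ± 0.042). In the mitosis list 0 rose and 10 fell of 37 tested members (0 and 15 adjusted over the list alone) (median -0.11, camera adjusted p = 5.2e-07, adjusted p = 0.224 with an estimated correlation). Apoptosis regulators were called: 4 rose and 0 fell of 15 tested members (4 and 0 adjusted over the list alone) (median 0.094, camera adjusted p = 0.005399), BMF rising from 19.5 ± 1.102 to 32.2 ± 1.43 CPM. Heat shock proteins fell in part: 0 rose and 7 fell of 15 tested members (0 and 7 adjusted over the list alone) (median -0.11, camera adjusted p = 2.7e-05, adjusted p = 0.141 with an estimated correlation). NRF2 targets rose in part: 6 rose and 0 fell of 22 tested members (8 and 1 adjusted over the list alone) (median 0.054, camera adjusted p = 0.00138, adjusted p = 0.141 with an estimated correlation). For luminal epithelial markers 0 rose and 3 fell of 11 tested members (0 and 4 adjusted over the list alone) (median -0.10, camera adjusted p = 0.00988, adjusted p = 0.117 with an estimated correlation). KRT19 was at -0.33 ± 0.052, and their summed level was 8877 ± 20.7 CPM. With PPT+PBDE100 replicate 2 set aside, risen and fallen members numbered 22 and 1 in the integrated stress response, 20 and 0 in cholesterol and 11 and 0 in fatty acid synthesis, 4 and 0 among metallothioneins, 0 and 16 in the interferon response and 6 and 0 in the AhR list. They numbered 8 and 0 in the estrogen-repressed, 10 and 12 (of 37 tested) in the estrogen-induced, 0 and 28 in the mitosis and 5 and 2 in the apoptosis list, 0 and 9 among heat shock proteins, 9 and 3 among NRF2 targets and 1 and 7 among luminal markers.

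The risen genes of largest change were CYP1A1, EGR1 (1.83 ± 0.16), ETV5, RUNX2, CYP1B1, ADM2, the immediate early gene FOS (1.34 ± 0.10), NUPR1, TNFRSF11B and ETV4, and the fallen ones IFIT1, OAS1, OAS2, DDX60, SAMD9, PARP9, PARP10, OAS3, BST2 and ISG15 (from 49.8 ± 7.45 to 20.5 ± 1.09 CPM). The call of BST2 was lost without PPT replicate 2 (adjusted p = 0.0946) or 3 (0.0867) and without PPT+PBDE153 replicate 1 (0.126) or 2 (0.0830). In total 1512 genes changed, 811 upward and 701 downward, 34 and 27 by at least 2-fold. The count was 4025 with PPT+PBDE100 replicate 2 set aside and 4181 when only these 2 groups were fitted, and it lay between 846 and 922 when any 1 of the 6 libraries was left out. With library-size scaling 64.0% of calls were upward, against 53.6%.

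**Figure D4:**
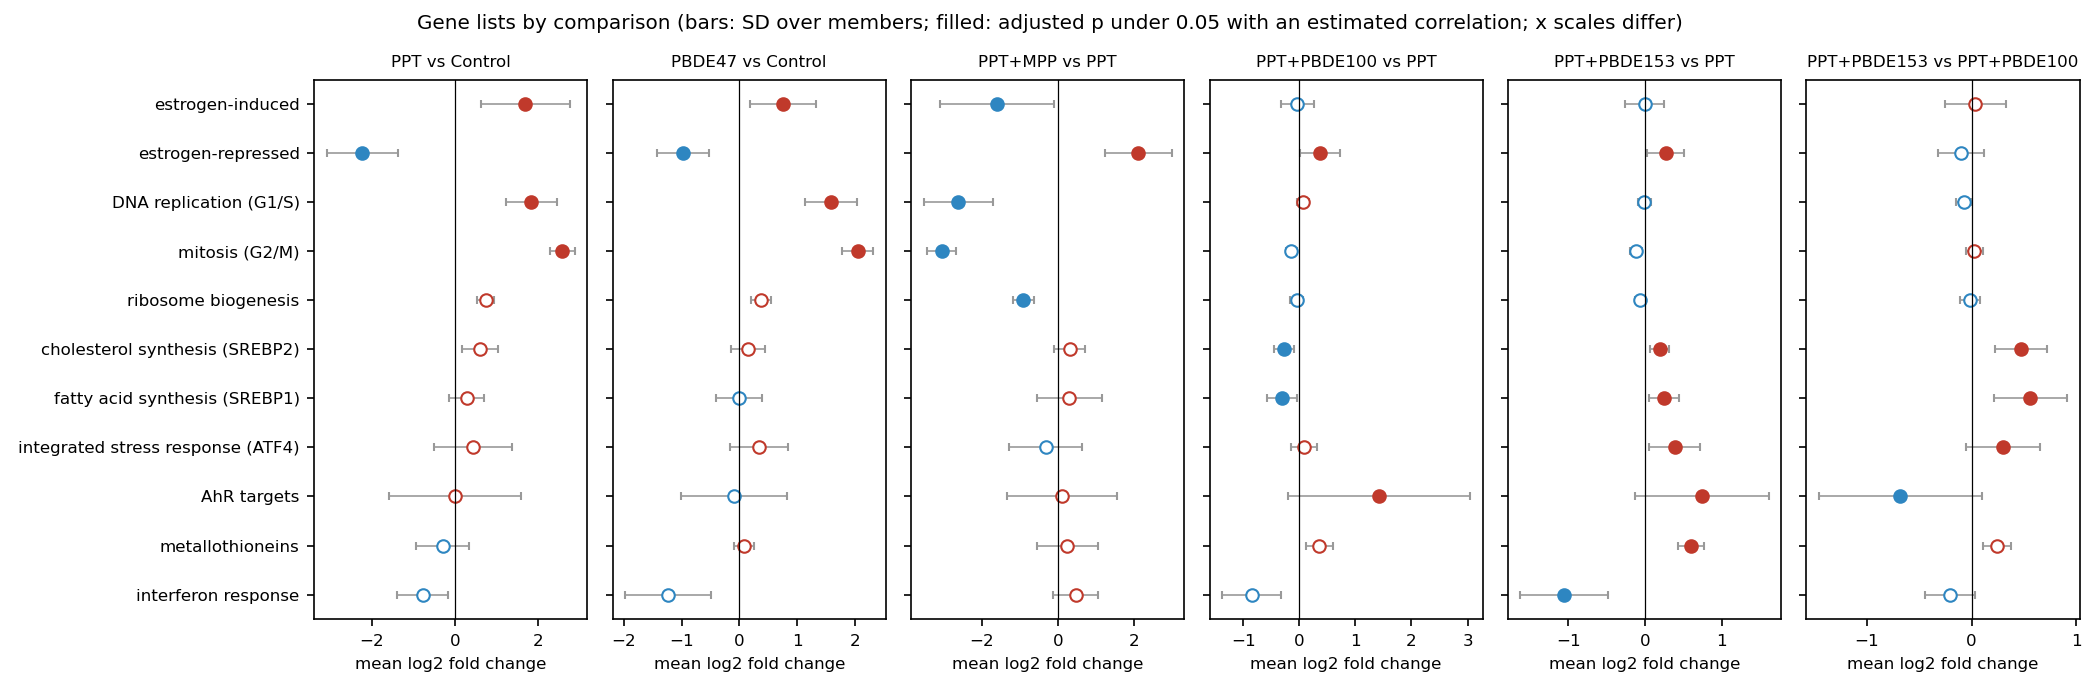
Mean log2 fold change of the tested members of 11 gene lists (± SD over members) in 6 comparisons, red above 0 and blue below, with scales that differ between panels. Filled dots mark lists with adjusted p under 0.05 with an estimated correlation, such as cholesterol synthesis, which is below 0 in PPT+PBDE100 against PPT and above 0 in PPT+PBDE153 against PPT.

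Of the 9995 genes changed by PPT, 1125 moved in the opposite direction with PBDE100 and 330 further in the same direction, where independent lists would give 619.4 and 618.9. With PBDE153 these were 846 and 408, where independent lists would give 529.1 and 528.7. Counting direction alone, 61.3% and 63.2% of the PPT-changed genes were opposite, against 53.6% for simulated unchanged groups that share simulated PPT libraries. The length trend of PPT+PBDE100 replicate 2 was not simulated. Correlations across genes, which are not independent replicates, were -0.29 and -0.21 (-0.0955 simulated), and covariances -0.0657 and -0.0451 (-0.0143 simulated), part of which may come from the shared PPT libraries. For PBDE100 the opposite and same counts were 2384 and 679 without PPT+PBDE100 replicate 2, where independent lists would give 1330.5 and 1330.9. They were 701 and 193, 649 and 167, and 653 and 163 without PPT replicate 1, 2 and 3, where independent lists would give 351.1, 324.3 and 319.0 opposite genes. For PBDE153 they were 2430 and 1062 with PPT+PBDE100 replicate 2 set aside, where independent lists would give 1543.8 and 1545.1. They were 497 and 255, 503 and 241, and 469 and 233 without PPT replicate 1, 2 and 3 (304.1, 305.2 and 283.8 opposite for independent lists), and 451 and 252, 503 and 240, and 482 and 235 without PPT+PBDE153 replicate 1, 2 and 3 (292.1, 309.2 and 296.8).

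PBDE153, which carries 1 bromine more than PBDE100, was compared with it directly, at the same dose, time and PPT background. Lipid synthesis and stress response genes were higher with PBDE153 and AhR targets higher with PBDE100. INSIG1 stood at 586 ± 4.91 CPM with PBDE153 and 330.4 ± 9.44 with PBDE100 (log2 fold change 0.83, SE 0.036, adjusted p = 6.0e-11). LPIN1 stood at 125 ± 3.19 and 61.7 ± 0.164 CPM (log2 fold change 1.02, SE 0.035, adjusted p = 2.1e-12), and SCD at 4316 ± 26.4 and 2135 ± 224 CPM (1.02). In the opposite direction, CYP1A1 stood at 6.300 ± 1.54 and 27.1 ± 1.18 CPM (log2 fold change -2.11, SE 0.12, adjusted p = 1.5e-09) and CYP1B1 at 90.2 ± 9.43 and 219 ± 22.3 CPM (-1.28). For cholesterol synthesis 20 rose and 0 fell of 24 tested members (22 and 0 adjusted over the list alone) (median 0.49, camera adjusted p = 1.7e-96). For fatty acid synthesis 11 rose and 0 fell of 14 tested members (12 and 0 adjusted over the list alone) (median 0.58, camera adjusted p = 2.6e-68). For the integrated stress response 14 rose and 0 fell of 27 tested members (18 and 1 adjusted over the list alone) (median 0.20, camera adjusted p = 4.2e-26). SLC7A11 was at 1.35 ± 0.075 and ASNS at 0.67 ± 0.050. In the AhR list 0 rose and 3 fell of 7 tested members (1 and 5 adjusted over the list alone) (median -0.48, camera adjusted p = 3.9e-14). AHRR was at -0.73 ± 0.10. The steroid metabolism list, which holds CYP1A1 and CYP1B1, was also called: 1 rose and 4 fell of 13 tested members (1 and 5 adjusted over the list alone) (median -0.13, camera adjusted p = 4.6e-10). So were p53 targets: 5 rose and 0 fell of 22 tested members (10 and 2 adjusted over the list alone) (median 0.11, camera adjusted p = 4.8e-04).

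PDZK1 was higher with PBDE153 (0.83 ± 0.060, adjusted p = 4.4e-08). For the other estrogen-regulated genes no difference was called, and the 95% intervals were 0.10 to 0.45 for TFF1, 0.028 to 0.53 for PGR, -0.057 to 0.31 for GREB1, -0.13 to 0.074 for CXCL12, -0.068 to 0.29 for MYC, -0.036 to 0.10 for CCND1 and -0.063 to 0.19 for ESR1. Without PPT+PBDE100 replicate 2, TFF1 was called (0.42, adjusted p = 2.3e-12), as it was by DESeq2 (0.28, adjusted p = 0.0290), by limma-voom (0.29, adjusted p = 0.0442), without a filter (0.0132) and without the batch term (0.0475). In the estrogen-induced list 6 rose and 3 fell of 36 tested members (9 and 7 adjusted over the list alone) (median 0.016, camera adjusted p = 0.0325, adjusted p = 0.236 with an estimated correlation), a call lost without PPT+PBDE100 replicate 1 (adjusted p = 0.0682) or PPT+PBDE153 replicate 3 (0.0604). The interferon response list was not called: 0 rose and 1 fell of 19 tested members (0 and 2 adjusted over the list alone) (median -0.15, camera adjusted p = 0.0926). Without PPT+PBDE100 replicate 1 it was (adjusted p = 0.0327), and STAT1 was at -0.0058 ± 0.11 (interval -0.23 to 0.22). In the mitosis list 0 rose and 0 fell of 37 tested members (0 and 0 adjusted over the list alone) (median 0.017, camera adjusted p = 0.292). Without PPT+PBDE100 replicate 2, members higher and lower with PBDE153 numbered 22 and 0 in cholesterol and 11 and 0 in fatty acid synthesis, 20 and 1 in the integrated stress response, 0 and 4 in the AhR list, 0 and 5 in steroid metabolism, 6 and 0 among p53 targets, 9 and 5 (of 37 tested) in the estrogen-induced, 0 and 1 in the interferon response and 2 and 0 in the mitosis list.

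The genes that were highest with PBDE153 relative to PBDE100 were PRUNE2 (1.82 ± 0.11), SLC7A11, ETV5, LPIN1 and CHAC1, and those lowest were UGT2B15, CYP1A1, PTGES (-1.35 ± 0.082), C10orf107 and NRK. The call of ETV5 was lost without PPT+PBDE153 replicate 1 (adjusted p = 0.0536), and with only these 2 groups fitted ETV5 and NRK were not called (0.0530 and 0.0684). In total 687 genes differed, 357 higher and 330 lower with PBDE153, 15 and 23 by at least 2-fold. The count was 1700, 1217 and 1661 without PPT+PBDE100 replicate 1, 2 and 3, 377, 404 and 364 without PPT+PBDE153 replicate 1, 2 and 3, and 114 when only these 2 groups were fitted. PBDE47 was given without PPT, so its values do not compare with these at matched conditions: against Control, the cholesterol and AhR lists had medians of 0.090 and -0.30 with PBDE47.

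**Figure D5:**
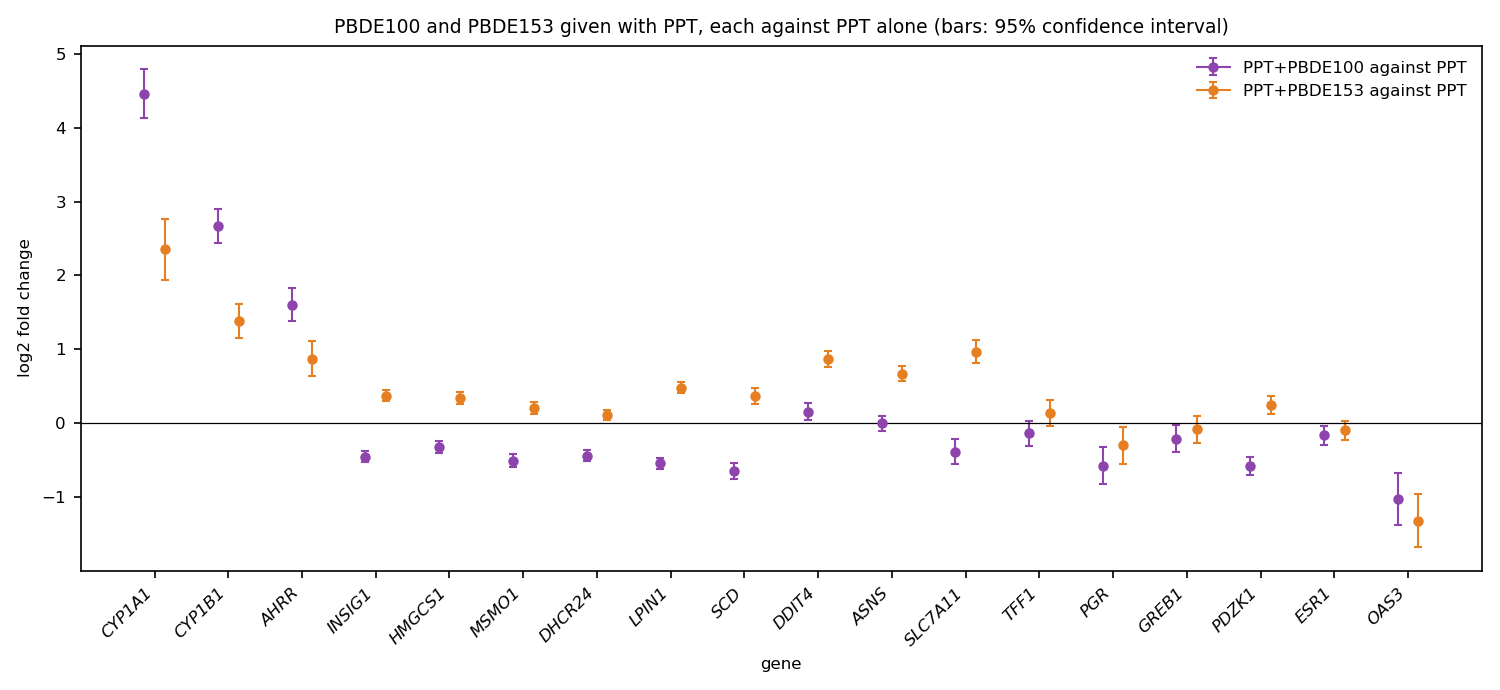
Log2 fold change (y axis, with 95% interval) of 18 genes (x axis) in PPT+PBDE100 against PPT and in PPT+PBDE153 against PPT (3 libraries per group). CYP1A1 stands at 4.46 and 2.35, and INSIG1 at -0.45 and 0.38.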

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

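Counts of splits and fits with 1 library left out were planned before the data were examined. The use of these fits below and the other tests were chosen after the results or the deviation of PPT+PBDE100 replicate 2 were seen. PBDE47 replicate 3, which the main comparisons leave out, had an estrogen-induced list level 0.67 above the highest Control library on the log2 scale, a signal in a library outside the main measurement.

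Lists that differed between the PBDE combinations were picked out because the direct comparison of PPT+PBDE153 with PPT+PBDE100 called them. The median log2 difference was 0.49 for cholesterol synthesis, 0.58 for fatty acid synthesis, 0.20 for the integrated stress response and -0.48 for AhR targets.

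PPT+PBDE100 replicate 2 stood apart from its group. Its log2 deviation from the other replicates followed gene length, with a Spearman correlation of -0.747 across expressed genes, which are not independent replicates, against at most 0.209 in size for libraries of the other groups. Against RNA from another cell type, the summed fibroblast, endothelial and immune markers were only 1.19 times those of its replicates, and against a label exchanged between groups, CYP1A1 stood at 25.8 CPM, above the 8.04 CPM of the highest library of the other groups. A length bias of that library, for example from RNA quality or library preparation, may account for the 53.7% of its deviation variance that follows length, and the rest remains open. No biological explanation was tested, since the design gives this library no condition of its own.

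The interferon response list was lower in PPT+PBDE153 than in PPT. A single high PPT library is argued against by a median log2 fold change of -0.89 or lower whichever PPT library was left out, and a length bias by -0.94 after the trend with length was removed, the same as before. The test of leaving out PPT libraries took the place of 2 others for high PPT libraries, of the medians in PPT+MPP against PPT (0.47) and in PPT against Control (-0.78), which could not decide, since MPP and PPT may act on the list themselves. PPT libraries that are all high remain untested. The medians in PPT+PBDE100 against PPT and PBDE47 against Control were -0.76 or lower, and in neither comparison did the mean log2 CPM of the list overlap between the groups compared. It was 2.46 to 2.63 in PBDE47 and 3.65 to 4.02 in Control, and 2.02 to 2.41 in PPT+PBDE100, 1.95 to 2.10 in PPT+PBDE153 and 2.79 to 3.23 in PPT. Both list calls were lost with an estimated correlation (adjusted p = 0.0619 and 0.332). The PBDE47 libraries also lay below every PPT library. A PPT-like action weaker than that of PPT would not give this if these genes followed its strength. With 1 dose of each compound that could not be tested. A lowering common to the 3 PBDEs may be involved. It stays open because PBDE47 was given only without PPT and the others only with it, and because of the list calls lost.

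Cholesterol synthesis genes were higher in PPT+PBDE153 than in PPT+PBDE100, from opposite changes against PPT. Without PPT+PBDE100 replicate 2 the median log2 difference was 0.53, and with the length trend removed 0.52, against 0.49 with all libraries, so neither that library nor length as tested accounts for it. A difference between the 2 congeners in their action on sterol-regulated transcription may underlie it, a hypothesis found and tested on the same libraries. Culture batches within the series are not given in the labels and remain untested.

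The 6 libraries of a comparison allow 10 splits, so 1 in 10, above 0.05, is the smallest share the design can give. Fitted on these alone with edgeR, the real split called 10729 genes for PPT and 8148 for PBDE47 against Control. It called 11146, 203 and 4181 for PPT+MPP, PPT+PBDE100 and PPT+PBDE153 against PPT, and 114 for PPT+PBDE153 against PPT+PBDE100. It called 4949, 8553 and 10690 for the same 3 combinations against Control, and 8126 for PBDE47 against PPT. The other splits called 0, but each mixes both groups, so a real effect widens their spread and they give no null count. Their highest counts at unadjusted p under 0.05 ran from 36 to 1236. The batch term gives PBDE47 replicate 3 no weight, so its comparisons are not 3 against 3.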

How the results depend on the processing

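The alternatives were fixed before the data were examined, except the length trend and PPT+PBDE100 replicate 2 set aside, which were chosen after seeing the data. Wherever no construction is named, the cause was not tested. Under the scaling, filter, DESeq2, limma-voom and batch alternatives the counts of changed genes stayed within 1.5 times the reported values in all 10 comparisons.

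A test for changes over 1.5-fold, a stricter question by construction, gave 3236 genes for PPT against Control, 968 for PBDE47 against Control, 3689 for PPT+MPP against PPT, 21 for PPT+PBDE100 against PPT, 21 for PPT+PBDE153 against PPT, 13 for PPT+PBDE153 against PPT+PBDE100, 306 for PPT+MPP against Control, 3006 and 3116 for PPT+PBDE100 and PPT+PBDE153 against Control and 510 for PBDE47 against PPT. Adjusted p under 0.01 left 745, 648, 311 and 2165 genes for PPT+PBDE100 against PPT, PPT+PBDE153 against PPT, PPT+PBDE153 against PPT+PBDE100 and PPT+MPP against Control. For the first 3 of these, limma on log2(FPKM + 1) gave 1124, 923 and 421 genes, on log2(FPKM + 0.1) 1122, 902 and 400, and without a filter 1007, 871 and 427. Fitting only the 2 groups compared gave 203, 4181, 114 and, for PPT+MPP against Control, 4949. Removing the length trend gave 2950, 2403 and 1130. With PPT+PBDE100 replicate 2 set aside, PPT+PBDE153 against PPT had 4025 and PPT+MPP against Control 5356 changed genes. Leaving out 1 library at a time gave 973 to 3468 for PPT+PBDE100 against PPT, 846 to 922 for PPT+PBDE153 against PPT and 364 to 1700 for PPT+PBDE153 against PPT+PBDE100. Without 1 first-batch PBDE47 library the other is assumed to vary like the other groups.

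Of 28 lists, camera called 13, 12, 14, 15, 15, 10, 9, 17, 16 and 15 for PPT against Control, PBDE47 against Control, PPT+MPP, PPT+PBDE100 and PPT+PBDE153 against PPT, PPT+PBDE153 against PPT+PBDE100, PPT+MPP, PPT+PBDE100 and PPT+PBDE153 against Control and PBDE47 against PPT. With an estimated correlation these were 8, 6, 7, 6, 8, 6, 5, 8, 9 and 5, and with fry, which does not compare with other genes, 25, 21, 25, 18, 21, 10, 20, 24, 25 and 22. The respiratory chain list in PPT+PBDE100 against PPT turned from higher to lower without PPT+PBDE100 replicate 2 (adjusted p = 0.817, against 4.8e-04 to 0.0537 with any other library of these groups left out).

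PPT-changed genes moved in the opposite direction by PBDE100 numbered 649 to 2384 with 1 library left out and 479 at adjusted p under 0.01. Counting direction only, they numbered 6131 (61.3%, against 53.6% for simulated unchanged groups that share simulated PPT libraries). For PBDE153 these were 451 to 761, 338 and 6320 (63.2%, against the same 53.6%), and 2430 with PPT+PBDE100 replicate 2 set aside. PBDE47 shared the direction of 9420 PPT-changed genes counting direction only (94.25%, against 53.03% for simulated unchanged groups that share simulated Control libraries). The difference in the estrogen-induced list level was 1.33 on log2(FPKM + 1), 1.71 with a prior count of 0.5 and 1.59 with library size alone for PPT against Control, 0.54 on log2(FPKM + 1) for PBDE47 against Control, and -1.16, -1.55 and -1.43 for PPT+MPP against PPT.

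Replicate numbers did not pair the libraries: 3 of 45 same-numbered pairs across groups had a correlation of deviations over 0.1 (median -0.0189, from -0.286 to 0.165), and 3 of 18 libraries had their best partner under their own number. With the replicate number as a block, the comparisons named first to last above had 9947, 6529, 10334, 1613, 1316, 622, 3130, 10018, 9822 and 6035 changed genes.

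Over 581 pairs of a named gene and a comparison, the call was the same in 579 with DESeq2 size factors, 574 with upper-quartile factors, 575 with library size alone, 572 without a filter, 572 with DESeq2, 579 with limma-voom, 578 without the batch term and 575 with the block. Of 528 pairs in the filtered FPKM table it was the same in 521 on log2(FPKM + 1). Fitting only the 2 groups compared ended 22 calls and added 18. Setting PPT+PBDE100 replicate 2 aside added 18 of 432. Over 3486 fits with 1 library left out, 56 calls were lost and 22 gained, and in no pair did a called direction reverse under the alternatives run. For lists these were 44 lost and 19 gained of 1680, and the block moved 6 of 280. Depth of 20413030 to 27176511 counts left genes under about 1 CPM with few reads, so their fold changes depend on the prior count.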

Other observations

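The tests of a single scale factor for PBDE47, of other cells as a source of CYP19A1 and of an added CYP19A1 copy were chosen after the result was seen. With MPP, PPT-treated cells did not simply return to Control. Cholesterol synthesis genes stood far above Control: 23 rose and 0 fell of 24 tested members (23 and 0 adjusted over the list alone) (median 1.00, camera adjusted p = 1.0e-101). HMGCS1 rose from 88.2 ± 1.61 to 224 ± 5.93 CPM (1.35 ± 0.038), INSIG1 from 265 ± 8.93 to 610.5 ± 13.8 CPM and SCD from 3012 ± 43.6 to 7273 ± 133 CPM, and in the fatty acid synthesis list 10 rose and 1 fell of 14 tested members (10 and 1 adjusted over the list alone) (median 0.56, camera adjusted p = 7.3e-32). DNA replication genes lay below Control: 0 rose and 37 fell of 40 tested members (0 and 39 adjusted over the list alone) (median -0.71, camera adjusted p = 8.0e-49), with CCNE2, a cyclin E gene, at -1.45 ± 0.079. Estrogen-induced genes split: 18 rose and 13 fell of 36 tested members (19 and 14 adjusted over the list alone) (median 0.21, camera adjusted p = 1.3e-07), with GREB1 below Control (-1.47 ± 0.090) and RAPGEFL1 above it (2.19 ± 0.042). PGR was at 0.22 ± 0.14 (adjusted p = 0.322). Among the genes of largest change were SERPINA1 (4.67 ± 0.25), FGFBP2, CD22, UCA1 and ANO1 upward and MAOB (-2.72 ± 0.15), IL20, PALD1 and BMPER downward. In total 3250 genes differed, 1618 upward and 1632 downward, and 5356 with PPT+PBDE100 replicate 2 set aside. The upward share of 49.8% was 42.2% with DESeq2 size factors, 42.9% with upper-quartile factors, 39.8% with library-size scaling, 40.7% without a filter and 40.6% with the stricter filter.

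Compared directly, PBDE47 alone left estrogen-induced genes below PPT, though doses and compounds differ: 2 rose and 32 fell of 36 tested members (2 and 33 adjusted over the list alone) (median -0.89, camera adjusted p = 2.6e-50). PGR was at -2.24 ± 0.15 and GREB1 at -1.45 ± 0.10. Estrogen-repressed genes were higher: 17 rose and 0 fell of 17 tested members (17 and 0 adjusted over the list alone) (median 1.12, camera adjusted p = 6.0e-31). Mitosis genes were lower by less: 0 rose and 37 fell of 37 tested members (0 and 37 adjusted over the list alone) (median -0.53, camera adjusted p = 8.9e-26). AURKA was at -0.704 ± 0.049. Cholesterol synthesis genes were lower: 0 rose and 21 fell of 24 tested members (0 and 21 adjusted over the list alone) (median -0.53, camera adjusted p = 1.5e-16). INSIG1 was at -0.80 ± 0.041. The genes of largest change were DLGAP1, CTGF, NAV3, MME and IL1R1 upward and GATA4, EGR3, SLC5A8, KIAA0125 and KLK11 downward. In total 6209 genes differed, 3033 upward and 3176 downward, and with library-size scaling 64.0% of calls were upward, against 48.8%. Against Control, both combinations kept the estrogen-induced response (36 of 36 members rose in each, 36 adjusted over the list alone), with medians of 1.48 for PPT+PBDE100 (10076 changed genes) and 1.58 for PPT+PBDE153 (9881).

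A hypothesis was that PBDE47 acts like PPT at a lower strength, with 1 scale factor for all genes. The slope of the PBDE47 on the PPT fold changes, after the covariance from simulated shared Control libraries was taken off, was 0.533. The mitosis list lay above it: its mean log2 fold change with PBDE47 was 2.04 where the slope gives 1.38, an excess of 0.66 against an SD of 0.132 over members. The G1/S list had an excess of 0.60 (SD 0.161). The interferon response list had the largest excess in size, -0.82 (SD 0.533), and estrogen-repressed genes had 0.21 (SD 0.162), a smaller fall than the slope gives. The estrogen-induced list had -0.15 (SD 0.331). These SDs are over members, which are not independent. A single factor thus does not describe the cell cycle lists, whose excess was several times that SD, which may reflect a dose-response that differs between gene groups or a further action of PBDE47. The data hold 1 dose of each compound, so these remain open.

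CYP19A1, which encodes aromatase, was picked out after its values were seen: it stood at 643 ± 23.2 CPM in Control, rank 134 among all genes, and at 617 to 947 CPM over the 18 libraries. RNA from placental or stromal cells is argued against, since the higher of the summed trophoblast and stromal marker levels in Control was 11.6 CPM (15 and 9 members in the tables; the most abundant were COL1A1 at 9.77 CPM and KRT7 at 1.66 CPM). A derivative of the line that carries an added CYP19A1 copy is a candidate explanation that gene counts, which do not show which part of the gene was read, cannot decide.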
